A study of Mus musculus with 12 samples.

How the data were processed

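RNA was measured in liver of C57BL/6 mice (Mus musculus) carrying floxed Sqstm1 or Tsc1 alleles, with or without a Cre transgene under the albumin promoter, which is active in hepatocytes. Per the labels' protocols, liver pieces were flash frozen, RNA was extracted with Trizol, poly(A) RNA was selected and libraries were made with a strand-directed kit. Sequencing was single-end with 75 nucleotides on an Illumina NextSeq 500 or paired-end on a HiSeq 2000, and which library ran on which instrument is not given in the sources used here. The design text names low-fat and high-fat diets without saying which sample had which. Age is not given in the sources used here, and no sample label states whether a piece was tumour or other tissue. The name under which the Tsc1Δhep and Tsc1/p62Δhep counts were deposited holds the word NORMAL after TSC1KO. What that word refers to is not explained there.

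The deposited files were 2 tables of gene counts made by the authors, each with 6 libraries, 1 holding p62F/F and p62Δhep and the other Tsc1Δhep and Tsc1/p62Δhep. All values were whole numbers and the library totals differed, so the deposited values were taken as counts with no normalization. The aligner, the counting tool, the annotation and whether strand was used in counting are not given in the sources used here. The submitters' processing notes name the human build hg19, whereas the tables' gene symbols are those of mouse. No coordinates of that build were used, and the order of genes along a chromosome was taken from the mouse RefSeq table of GRCm38. Each table had 23420 genes named by symbol. Of these, 21571 matched a symbol of the mouse RefSeq table, 1686 an older symbol and 163 neither, so 99.3% matched. Of all, 27 names had been turned into dates, as spreadsheet programs do, and held 0.143% to 0.310% of the counts. They stayed in the tests and are never named, and 5 of them were called in the comparison of Tsc1/p62Δhep with Tsc1Δhep. There were 5787 genes with no count in any library, and no mitochondrially encoded gene was listed.

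Samples were put into groups and numbered by their titles. Replicates were compared before averaging. A chi-square statistic of each pair of libraries of a group, over genes with at least 20 counts, was 36.2 to 325 per gene, so no pair agreed within sampling noise and none was counted as 1 sample. Comparisons were fitted within a table, because each table may have been processed apart. Levels set side by side across tables were not tested.

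The groups, the comparisons, the tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Genes were kept with edgeR's filterByExpr (at least 10 counts in a group's number of libraries after scaling, and 15 in total), libraries were scaled by TMM, and differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p below 0.05. CPM values use these scaled library sizes, except where levels of both tables are set side by side, which use the library totals. The difference of the p62 effect between Tsc1 backgrounds was the interaction contrast of 1 model of all 12 libraries. In it, a factor that scales a whole table cancels. An effect of the Cre transgene does not cancel, because by the titles only p62F/F lacked it.

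The rule for named genes took Sqstm1, Tsc1, Alb, Nfe2l2, Keap1 and Myc in each comparison. It added the 8 largest rises and the 8 largest falls among genes with an adjusted p below 0.05, a mean of at least 50 counts and no overlap between groups, or, where fewer than 3 genes passed, the 8 with the smallest p. It also added, for each list with at least 3 members past the threshold, the 3 members with the smallest p, and for the interaction the 6 genes with the smallest p. Not all of these genes are named in the text. The result of 1 further list member is not reported here. Genes outside the rule that are named with a change were chosen after their values were seen, whether or not the text repeats it there. Of the named genes called in the comparison of Tsc1/p62Δhep with Tsc1Δhep, 69 of 92 kept their call without each library in turn and 23 lost it in at least 1 such fit, and the examples given are mostly among the 69.

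There were 40 gene lists. The pathway lists were NRF2 targets, MYC targets, glycolysis, gluconeogenesis and glycogen, cholesterol synthesis, lipogenesis, PPARα and fatty acid oxidation, bile acids, drug-metabolising cytochromes, the unfolded protein response, ATF4 targets, p53 targets, cell cycle, fibrosis and matrix, oncofetal and liver tumour markers, acute phase, NF-κB and cytokines, interferon, autophagy and lysosome, respiratory chain, ribosomal proteins, proteasome, circadian clock, male-biased, female-biased and immediate early genes. The cell type lists were pericentral, periportal, hepatocyte, cholangiocyte and progenitor, stellate, endothelial, macrophage and Kupffer, T and NK, B and plasma, neutrophil, erythroid, pancreas, adipocyte and muscle. Some lists share genes: the pericentral list shares 1 gene and the periportal list 3 genes with the hepatocyte list. Lists with at least 3 tested genes were tested with limma's camera on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. The level of a list in a library is the median over its genes of the log2 CPM minus that gene's mean in the table.

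Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Alternatives were DESeq2, its size factors in edgeR, no filter on low counts, a mean of at least 50 counts, robust dispersion, limma on log2(CPM + 1) with a trend, the replicate number as a block, 1 fit of all 12 libraries, and leaving out each library in turn. Added after seeing the data were limma with each library's trend by GC content and transcript length removed, 1 surrogate variable, Rn45s left out, and leaving out Tsc1Δhep library 3 and Tsc1/p62Δhep library 1 together.

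The scripts were tested on counts simulated from the real means and library sizes, with known changes in a seeded set of genes. At each fold 64 to 67 changed genes were tested. In the comparison of p62Δhep with p62F/F (12460 genes) 1.52% of 1.5-fold, 35.8% of 2-fold and 83.1% of 4-fold changes were recovered, with 8 false calls. In the comparison of Tsc1/p62Δhep with Tsc1Δhep (12481 genes) 0%, 0% and 57.8% were recovered with 7 false calls, and in the interaction (13074 genes) 0%, 1.52% and 31.8% with 2 false calls. With no list changed, camera called 1 of 35 lists in the first of these and 0 of 36 and 0 of 37 in the others. The simulated genes were drawn independently of one another, so this could not show false list calls that correlated genes give. Total counts were 15792048 to 33377247 per library, and the spread between libraries of a group exceeded counting error. A gene at 0 in a group was given a lower bound from a floor of 3 counts over the group's 3 libraries, and ratios on 1 to 3 counts a 95% counting interval.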

Results

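The data were 12 poly(A) RNA-seq libraries of mouse liver in 4 groups of 3. Floxed mice with no Cre recombinase (p62F/F) were set beside mice whose p62 gene, Sqstm1, was deleted in hepatocytes by Cre under the albumin promoter (p62Δhep). Mice with the same kind of deletion of Tsc1 (Tsc1Δhep) were set beside mice lacking both genes in hepatocytes (Tsc1/p62Δhep). Sqstm1 encodes p62, an adaptor of selective autophagy that also binds KEAP1, the inhibitor of the antioxidant transcription factor NRF2. Tsc1 encodes a subunit of the complex that restrains the growth kinase mTORC1. Each pair of groups had its own table of counts, and levels given as CPM, the counts scaled to library size, are means ± SD with n = 3 libraries per group, scaled within that table.

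Total counts were 19832184, 20763224 and 18062844 in p62F/F libraries 1 to 3 and 18339067, 17539987 and 25273631 in p62Δhep. They were 21742865, 33377247 and 17492176 in Tsc1Δhep and 15792048, 17000255 and 17809454 in Tsc1/p62Δhep. Between 14487 and 15681 genes had at least 1 count in a library. The ribosomal RNA precursor Rn45s took 1.91% to 3.50% of the counts in the p62F/F and p62Δhep libraries and 0.0751% to 0.158% in Tsc1Δhep. In Tsc1/p62Δhep libraries 1 to 3 it took 1.21%, 0.0872% and 0.181%. In a principal component analysis of the p62F/F and p62Δhep libraries the first component held 44.0% of the variance and did not separate the groups, whereas that of the Tsc1Δhep and Tsc1/p62Δhep libraries held 73.5% and did. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Intervals and lower bounds on counts cover counting error only.

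The targeted genes were read first in each library. Sqstm1 stood at 316, 351 and 349 CPM in the p62F/F libraries and at 17.5, 12.4 and 19.8 CPM in p62Δhep. It stood at 1210, 789 and 1002 CPM in Tsc1Δhep and at 14.4, 17.4 and 19.6 CPM in Tsc1/p62Δhep. Tsc1 was at 26.0 to 39.7 CPM in the p62F/F and p62Δhep libraries and at 5.39 to 13.7 CPM in the Tsc1Δhep and Tsc1/p62Δhep libraries, each scaled within its own table. Tsc1Δhep library 3 had 10.9 CPM of Tsc1, against 5.76 and 5.39 CPM in libraries 1 and 2 of that group.

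**Figure D1:**
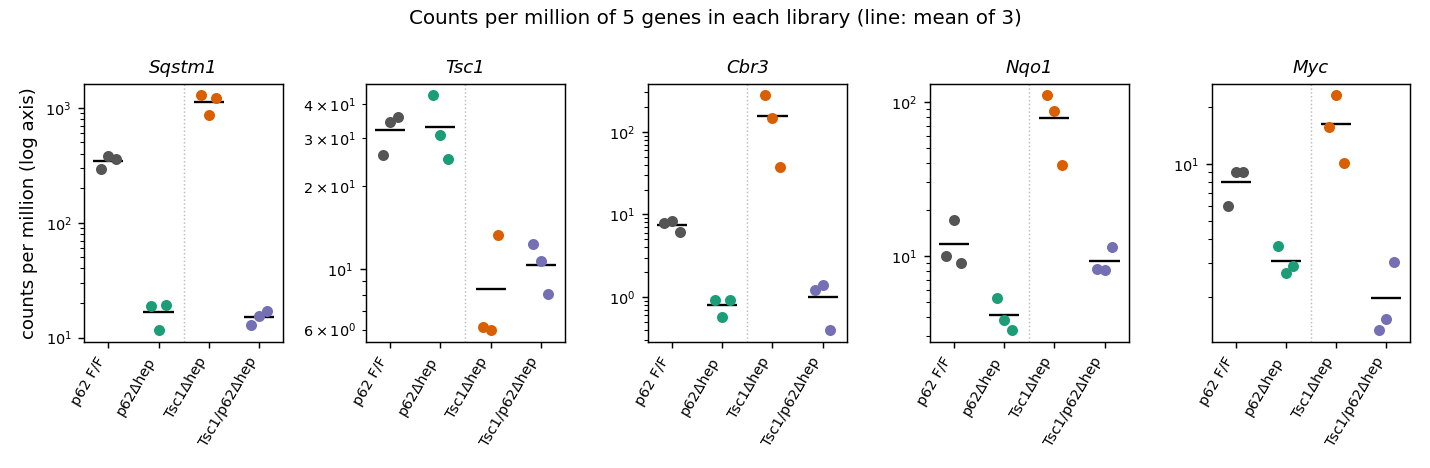
Level of Sqstm1, Tsc1, Cbr3, Nqo1 and Myc in each of the 12 libraries, as CPM on a log axis from library totals without scaling factors, with a point per library and a line at the mean of the 3 libraries of a group. Sqstm1 was at 19.2 CPM or less in each library whose label names a p62 deletion and at 292 CPM or more in the others.

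The first comparison asked what losing p62 did in hepatocytes whose Tsc1 gene was intact. By the titles p62F/F had no Cre and p62Δhep did, so loss of p62 and presence of Cre cannot be told apart in it. Whether diet, age, strain background, sequencer or library batch also differed between these groups was not tested and stays open. Sqstm1 itself fell 20.4-fold, from 339 ± 20.1 to 16.6 ± 3.81 CPM. The other gene past the threshold, Cbr3, a carbonyl reductase transcribed by NRF2, fell 9.05-fold from 7.40 ± 1.23 to 0.802 ± 0.172 CPM. Beyond these, genes of the NRF2 antioxidant programme, oncofetal and liver tumour markers, cell cycle genes and interferon-stimulated genes lay lower in p62Δhep as lists, and genes of the unfolded protein response lay higher. No list call held with an estimated correlation between genes.

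By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 of 12567 genes were lower and 0 were higher at an adjusted p below 0.05. Sqstm1 had a log2 fold change of -4.35 ± 0.21 (SE) with an adjusted p of 0.000963, and Cbr3 one of -3.18 ± 0.27 with an adjusted p of 0.0247. At an unadjusted p below 0.05 there were 1020 genes, where 628 would be expected by chance, and the groups did not overlap for 12.8% of genes, where chance gives 10%. DESeq2 called 32 genes higher and 150 lower, and limma on log2(CPM + 1) called 0 higher and 4 lower. Without p62F/F library 1, edgeR called 1 higher and 48 lower. Without each of the other 5 libraries in turn it called 0 higher and 1 lower. The Cbr3 call was lost without p62F/F library 2 (adjusted p 0.0964), p62F/F library 3 (0.0561), p62Δhep library 1 (0.0823), library 2 (0.132) or library 3 (0.0947). It was also lost with the replicate number as a block (0.349) and with all 12 libraries in 1 fit (0.247).

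Other genes named beforehand did not pass the test. Tsc1 (log2 fold change 0.05, adjusted p 0.958) and Keap1 (0.05, adjusted p 0.928) differed by less than the spread between libraries. Without p62F/F library 1 the Tsc1 value was -0.02, and without p62Δhep library 1 it was -0.10. Nfe2l2, the gene of NRF2, had -0.04 (adjusted p 0.968), which became 0.07, 0.02 and 0.03 without p62F/F library 2, p62F/F library 3 and p62Δhep library 2. Alb had -0.72 (adjusted p 0.728). Myc was at 7.91 ± 1.27 CPM in p62F/F and 3.09 ± 0.295 CPM in p62Δhep (log2 fold change -1.35, adjusted p 0.233 by edgeR and 8.38e-05 by DESeq2). The next smallest p-values, also not past the threshold, belonged to Limd2 (log2 fold change -1.03, adjusted p 0.0724), Ifi202b (0.0756), Fam84b (-1.08, 0.17), Anxa13 (-3.69, 0.213), Tceal8 (-1.39, 0.229) and Scn8a (-2.42, 0.233), each of which DESeq2 called. Without p62F/F library 1, 5 of these 6 passed, with adjusted p of 0.0447 for Limd2, 0.0356 for Ifi202b, 0.0404 for Fam84b, 0.0460 for Anxa13 and 0.0356 for Scn8a. Ifi202b, an interferon-inducible gene, had 175 counts over the p62F/F libraries (2.96 ± 0.617 CPM) and 0 in p62Δhep, which is at least 59.8-fold lower with a floor of 3 counts over the group.

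Of the 31 NRF2 targets tested, 1 fell by edgeR, Cbr3, and 11 fell when adjusted over the list alone. DESeq2 called 10 lower over all genes. The list median was -0.45 on the log2 scale (camera adjusted p 3.72e-09; adjusted p = 0.586 with an estimated correlation). The members past the threshold over the list alone, chosen after their values were seen, included the quinone reductase Nqo1 (11.8 ± 3.63 to 4.12 ± 0.745 CPM), the glutathione S-transferases Gsta2 (12.3 ± 7.02 to 1.58 ± 1.26 CPM) and Gstm1 (1057 ± 326 to 434 ± 78.3 CPM), and the cystine transporter Slc7a11 (9.38 ± 6.22 to 0.438 ± 0.430 CPM). The Gst genes have close paralogs, and their single values are uncertain. The hepatocyte markers moved the same way on balance (median -0.19, camera adjusted p 0.0438; adjusted p = 0.586 with an estimated correlation), with 0 of 16 past the test. Leaving out p62F/F library 1 (0.168), p62Δhep library 2 (0.271) or p62Δhep library 3 (0.364) ended the hepatocyte call, and the list's level in p62Δhep library 1, at 0.22, lay above those of p62F/F, at 0.07 to 0.18.

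Oncofetal and liver tumour markers had a median of -2.94 over 13 genes (camera adjusted p 7.82e-06; adjusted p = 0.586 with an estimated correlation). None passed over all genes tested by edgeR, whereas 9 fell and 1, Peg3, rose when adjusted over the list alone. Of these, chosen after their values were seen, the desaturase gene Scd2 went from 113 ± 75.3 to 11.04 ± 3.05 CPM, Akr1c18 from 53.1 ± 33.4 to 1.86 ± 1.73 CPM and Tff3 from 20.4 ± 13.2 to 1.83 ± 1.28 CPM. The median level of the list, against its mean in the table, was -0.29 in p62F/F library 1 but 1.24 and 1.59 in libraries 2 and 3 of that group, and -1.21 to -0.76 in p62Δhep. Cell cycle genes had a median of -0.51 over 28 genes, with none past the test over the list alone (camera adjusted p 8.35e-06; adjusted p = 0.586 with an estimated correlation). Their level was 0.75 in p62F/F library 3 and 0.22 in library 2, whereas that of p62F/F library 1, at -0.21, lay among those of p62Δhep, at -0.27 to -0.02.

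The unfolded protein response of the endoplasmic reticulum lay higher in p62Δhep, with a median of 0.74 over 20 genes (camera adjusted p 1.69e-08; adjusted p = 0.586 with an estimated correlation). None of the 20 passed over all genes by edgeR, where DESeq2 called 8 higher. By edgeR 10 rose when adjusted over the list alone. Among these, chosen after their values were seen, the chaperone Hspa5 went from 1721 ± 280 to 3369 ± 1179 CPM and Creld2 from 69.2 ± 14.8 to 250 ± 156 CPM. The rise lay in p62Δhep libraries 2 and 3, whose median levels for the list were 0.61 and 0.65. That of p62Δhep library 1, at -0.22, lay among the p62F/F libraries, at -0.57 to -0.19. Macrophage markers stood at 0.21 and 0.39 and acute phase genes at 0.85 and 0.79 in p62Δhep libraries 2 and 3, against -0.23 and -0.80 in p62Δhep library 1.

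Interferon-stimulated genes had a median of -0.35 over 26 genes, with none past the test over all genes and 5 that fell over the list alone (camera adjusted p 6.59e-06; adjusted p = 0.586 with an estimated correlation). They included Irf7 (56.1 ± 5.37 to 33.7 ± 4.38 CPM) and Ifit1 (18.6 ± 5.85 to 9.23 ± 2.68 CPM), chosen after their values were seen. The interferon list level of p62F/F library 1, at -0.02, and that of p62Δhep library 1, at -0.01, lay together. Liver genes known to be higher in females had a median of -2.16 over 7 genes, of which 1, Cyp2a4, fell over the list alone (camera adjusted p 0.00131; adjusted p = 0.586 with an estimated correlation). Their level was 2.98 in p62F/F library 2, against -0.12 and 0.65 in libraries 1 and 3 of that group and -1.79 to -0.37 in p62Δhep. Proteasome subunits had a median of 0.11 over 27 genes, none past the test over the list alone (camera adjusted p 0.00130; adjusted p = 0.586 with an estimated correlation). These lists, with the NRF2, oncofetal, cell cycle and unfolded protein lists, kept their call without each of the 6 libraries in turn.

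As for the hepatocyte list, each of the remaining 10 list calls ended when some library was left out, and in each but the erythroid list the levels of the groups overlapped. Macrophage markers (median 0.38, adjusted p 0.00177) lost the call without p62Δhep library 3 (0.0803), and cholangiocyte and progenitor markers (-0.46, 0.0343) without p62Δhep library 1 (0.252). Drug-metabolising cytochromes (-0.69, 0.00902) lost it without p62F/F library 2 (0.147) or p62Δhep library 2 (0.0804), and MYC targets (0.19, 0.0151) without p62F/F library 2 (0.0942) or p62Δhep library 3 (0.115). Acute phase genes (0.51, 0.01005) lost it without p62F/F library 2 (0.774) or p62Δhep libraries 2 (0.212) or 3 (0.146), and ATF4 targets (-0.27, 0.0358) without p62F/F library 3 (0.147) or p62Δhep libraries 1 (0.449) or 2 (0.0977). Immediate early genes (-0.37, 0.0343), which respond to handling, lost it without p62F/F libraries 1 (0.0940) or 3 (0.181) or p62Δhep library 1 (0.205). Stellate markers (0.21, 0.0343) lost it without p62F/F libraries 1 (0.748) or 3 (0.0671) or p62Δhep libraries 1 (0.321) or 2 (0.0977). Periportal markers (-0.24, 0.0366) lost it without p62F/F libraries 1 (0.442) or 3 (0.175) or p62Δhep libraries 1 (0.0552), 2 (0.0829) or 3 (0.233). Erythroid markers (-0.99 over 3 genes, 0.0343) lost it without p62F/F libraries 1 (0.127) or 3 (0.110) or p62Δhep libraries 1 (0.0673), 2 (0.0642) or 3 (0.0794). With an estimated correlation the adjusted p was 0.770 for stellate markers, 0.822 for acute phase genes and 0.586 for the other 8 of these lists.

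Of the 10, members past the threshold over the list alone were found in 4: Slc7a11 and Phgdh, a serine synthesis enzyme, among ATF4 targets, Tspan8 and Prom1 among cholangiocyte and progenitor markers, Fos and Egr1 among immediate early genes, and 1 erythroid gene, all lower in p62Δhep. In total 18 of 36 lists tested were called, 6 higher and 12 lower, and 0 were called with an estimated correlation, where the lowest adjusted p was 0.586. With limma's fry, which asks whether a list's genes move 1 way on balance, 0 were called (lowest adjusted p 0.259). For a change in either direction fry called 1, the NRF2 targets (adjusted p 0.0102).

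The 18 lists not called in p62Δhep had camera adjusted p-values from 0.104 to 0.990. They were glycolysis, gluconeogenesis and glycogen, cholesterol synthesis, lipogenesis, PPARα and fatty acid oxidation, bile acids, p53 targets, fibrosis, NF-κB, autophagy and lysosome, respiratory chain, ribosomal proteins, circadian clock, male-biased genes, and pericentral, endothelial, T and NK cell and neutrophil markers. Tbx3, a pericentral transcription factor, rose when adjusted over its list alone. The median and mean differed in sign for glycolysis (0.02 and -0.10), fibrosis (0.02 and -0.06), autophagy and lysosome (0.01 and -0.01), male-biased genes (-0.02 and 0.08) and the respiratory chain (-0.00 and 0.01). For T and NK cells (-0.18) and neutrophils (-0.09) camera's direction was up although the median was negative. Markers of B and plasma cells (2 tested), adipocytes (2), pancreas (1) and muscle (0) had too few genes for a list test.

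**Figure D2:**
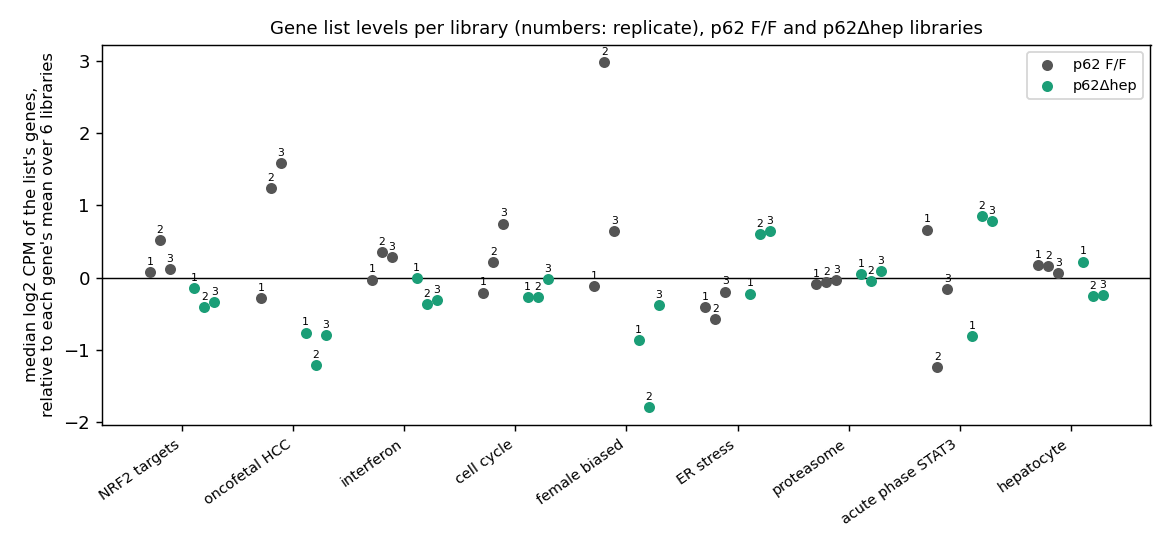
Median log2 CPM of the genes of selected lists, relative to each gene's mean over the 6 libraries, for each p62F/F and p62Δhep library, with a point per library. The unfolded protein response list lay at -0.22 in p62Δhep library 1 and at 0.61 and 0.65 in libraries 2 and 3.

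The second comparison asked what losing p62 did in hepatocytes that already lacked Tsc1. As lists, oncofetal and liver tumour markers, proliferation genes, matrix genes, amino acid stress genes driven by ATF4 and macrophage markers lay lower in Tsc1/p62Δhep, and genes of differentiated hepatocytes, bile acid transport, drug metabolism and pericentral identity lay higher. No list call held with an estimated correlation between genes, and in each of these lists but the oncofetal one some genes did not pass the test. Cd44, a cell surface receptor, fell 16.3-fold from 66.3 ± 9.44 to 4.07 ± 0.317 CPM, and Mki67, a proliferation marker, fell from 12.1 ± 4.48 to 1.01 ± 0.229 CPM. Cyp1a2, a pericentral cytochrome, rose 37.4-fold from 22.8 ± 9.43 to 850 ± 119 CPM, and the bile acid transporter Slc10a1 rose 17.5-fold from 50.4 ± 22.3 to 882 ± 161 CPM. Sqstm1 fell 58.4-fold, from 1000 ± 211 to 17.1 ± 2.61 CPM.

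By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1167 of 12620 genes were higher and 1886 lower in Tsc1/p62Δhep, 917 and 1749 of them by more than 2-fold, and the groups did not overlap for 45.7% of genes, where chance gives 10%. The counts moved without Tsc1Δhep library 2 (448 higher and 1162 lower), Tsc1Δhep library 3 (2686 and 3139), Tsc1/p62Δhep library 1 (351 and 760), library 2 (384 and 798) or library 3 (666 and 1219). Tsc1Δhep library 3 had the most Tsc1 of its group, and Tsc1/p62Δhep library 1 had the most Rn45s of its group. With both of these left out, a choice made after seeing the data, 1455 were higher and 1889 lower. Higher genes made up 38.2% of the calls, and 43.2% with limma on log2(CPM + 1) (1357 higher and 1787 lower). They made up 53.5% with limma and each library's trend by GC content and transcript length removed (2262 higher and 1967 lower). That removal was also chosen after seeing the data.

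Among the genes named beforehand, Myc fell 6.51-fold, from 14.6 ± 6.22 to 2.23 ± 1.11 CPM (log2 fold change -2.70 ± 0.48 SE, adjusted p 0.00769). Sqstm1 had a log2 fold change of -5.87 ± 0.31 (adjusted p 0.000366). Nfe2l2 had 0.02 (adjusted p 0.944), which became -0.00 without Tsc1Δhep library 1 and -0.04 without Tsc1/p62Δhep library 2. Keap1 had 0.64 (41.0 ± 6.94 and 63.7 ± 7.62 CPM, adjusted p 0.0650) and passed without Tsc1Δhep library 3 (0.0127), with DESeq2 (0.0336) and with all 12 libraries in 1 fit (0.00917). Tsc1 had 0.66 (7.36 ± 3.10 and 11.6 ± 2.19 CPM, adjusted p 0.188) and passed without Tsc1Δhep library 3 (0.0178). Alb had 1.21 (adjusted p 0.0907) and passed without Tsc1Δhep library 2 (0.0235) and with DESeq2 (0.0258).

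The largest rises among genes with separate groups belonged to the urinary protein genes Mup12, Mup7, Mup14 and Mup1, to Hsd3b5, Lrtm1, the transporter Slco1a1 and Serpina4-ps1. Lrtm1 rose from 0.0536 ± 0.0303 to 18.1 ± 11.3 CPM (adjusted p 0.00104) and Slco1a1 182-fold from 1.40 ± 0.990 to 262 ± 169 CPM (adjusted p 0.00219). Mup12, Mup1 and Hsd3b5 rested on 1, 2 and 3 counts in Tsc1Δhep against 2850, 1081 and 793 in Tsc1/p62Δhep, with 95% counting intervals for the ratio of 927 to 204269, 271 to 8106 and 163 to 2330. The Mup and Serpina genes have near-identical copies, and their single values are uncertain. The largest falls included Wnt16, a WNT ligand, which had 619 counts in Tsc1Δhep (7.96 ± 4.10 CPM) and 0 in Tsc1/p62Δhep, at least 114-fold lower with a floor of 3 counts over the group (adjusted p 0.00259). Tm4sf20 (at least 111-fold lower, adjusted p 0.00578) and Myot (at least 118-fold, 0.00497) were also at 0. Serpinb9e (at least 104-fold, 0.0293) and Guca2a (at least 145-fold, 0.0499) were at 0 too, but their calls were lost without any of Tsc1/p62Δhep libraries 1, 2 or 3, with adjusted p of 0.0767, 0.0731 and 0.0708 for Serpinb9e and 0.114, 0.109 and 0.106 for Guca2a. Serpinb9e has close paralogs and is uncertain. Tmem116 had 2 counts in Tsc1/p62Δhep against 43.6 ± 19.5 CPM in Tsc1Δhep, a ratio of 906 with a 95% counting interval of 251 to 7487. The other 2 of the 8 largest falls were genes with no name.

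Each of the 14 oncofetal and liver tumour markers tested fell, over all genes and when adjusted over the list alone, with a median of -4.31 (camera adjusted p 1.16e-08; adjusted p = 0.196 with an estimated correlation). Besides Cd44 (log2 fold change -4.03 ± 0.23 SE, adjusted p 0.000366), the oncofetal RNA-binding protein gene Igf2bp3 went from 19.7 ± 3.92 CPM to 1 count, a ratio of 856 with a 95% counting interval of 153 to 33837. Tff3 fell from 650 ± 342 to 0.883 ± 0.825 CPM (log2 fold change -9.51). Of the 30 cell cycle genes, 17 fell and 19 fell when adjusted over the list alone (median -2.27, camera adjusted p 2.03e-08; adjusted p = 0.339 with an estimated correlation). Top2a (-3.52) and Cenpf (-3.04) fell with Mki67 (-3.58). Of the 26 matrix and fibrosis genes 16 fell and 1 rose, with the same counts when adjusted over the list alone (median -2.01, camera adjusted p 0.00111; adjusted p = 0.512 with an estimated correlation). Loxl2 (37.5 ± 8.74 to 1.95 ± 0.502 CPM) and Col4a1 (143 ± 67.1 to 14.3 ± 1.82 CPM) fell, and Col5a2 rose from 30.8 ± 14.6 to 197 ± 37.4 CPM. Bile duct and progenitor markers were called lower as a list (4 of 11 fell, 5 when adjusted over the list alone, median -1.95, camera adjusted p 0.00588; adjusted p = 0.523 with an estimated correlation), among them Spp1, from 2707 ± 2271 to 95.4 ± 21.7 CPM. The level of that list in Tsc1Δhep library 2, at -0.58, lay among those of Tsc1/p62Δhep, at -1.03 to -0.47, against 1.67 and 0.77 in Tsc1Δhep libraries 1 and 3.

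Among antioxidant and stress genes, NRF2 and ATF4 targets were lower in Tsc1/p62Δhep. Of 31 NRF2 targets 12 fell and 2 rose, over all genes and when adjusted over the list alone (median -0.60, camera adjusted p 0.00434; adjusted p = 0.512 with an estimated correlation). The transporter Abcc4 fell from 149 ± 58.9 to 6.46 ± 0.520 CPM, G6pdx, of the pentose phosphate pathway, from 38.5 ± 10.02 to 5.96 ± 2.00 CPM, and Slc7a11 from 170 ± 86.3 to 0.501 ± 0.444 CPM. Of 21 ATF4 targets 14 fell and 1 rose, or 15 and 2 when adjusted over the list alone (median -2.84, camera adjusted p 1.63e-05; adjusted p = 0.263 with an estimated correlation). They included Mthfd2, of mitochondrial folate metabolism (41.3 ± 6.37 to 1.11 ± 0.437 CPM), Pck2 (37.8 ± 10.02 to 3.32 ± 1.29 CPM) and the hormone Fgf21 (43.4 ± 6.45 to 1.20 ± 1.13 CPM). The unfolded protein response list was not called (median -0.50, adjusted p 0.240). It had 5 genes that fell and 1 that rose, or 6 and 3 when adjusted over the list alone, and 4 of its 20 genes, Ddit3, Atf3, Trib3 and Chac1, are also ATF4 targets.

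Macrophage, interferon and NF-κB lists were lower in Tsc1/p62Δhep. Of 19 macrophage and Kupffer cell markers 14 fell, or 14 with 1 that rose when adjusted over the list alone (median -1.63, camera adjusted p 0.000270; adjusted p = 0.263 with an estimated correlation). Cd68 fell from 21.6 ± 4.71 to 2.98 ± 0.631 CPM, Itgam from 6.37 ± 1.94 to 0.781 ± 0.134 CPM and Ctss from 85.1 ± 31.7 to 15.0 ± 1.77 CPM. Of 26 interferon-stimulated genes 13 fell and 1 rose, with the same counts when adjusted over the list alone (median -1.11, camera adjusted p 0.00224; adjusted p = 0.563 with an estimated correlation), among them Ifit2 (-3.30) and Mx1 (-3.05). Of 15 NF-κB and cytokine genes 7 fell and 1 rose, or 9 and 1 when adjusted over the list alone (median -1.39, camera adjusted p 0.00254; adjusted p = 0.328 with an estimated correlation), among them the adhesion molecule Icam1 (-2.33), Tnfaip3 (-2.41) and Cxcl16 (-2.60). Endothelial markers were not called (median 0.14, adjusted p 0.718). Stellate markers were called higher (median 1.35, adjusted p 0.0407; adjusted p = 0.720 with an estimated correlation), with Ecm1 up by 2.86 and Rgs5 at -2.51 on the log2 scale, both chosen after their values were seen, over all genes and when adjusted over the list alone. That call was lost without Tsc1Δhep library 1 (0.107) or Tsc1/p62Δhep library 3 (0.0719). Tsc1Δhep library 1 stood apart in these cell types, with list levels of -2.93 for stellate, -1.29 for endothelial and -3.81 for pericentral markers.

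Lists of differentiated liver genes were higher in Tsc1/p62Δhep. Of 17 hepatocyte markers 12 rose, or 14 when adjusted over the list alone (median 1.98, camera adjusted p 2.19e-07; adjusted p = 0.196 with an estimated correlation), such as Hpd, of tyrosine breakdown (644 ± 161 to 2704 ± 236 CPM), and Cyp3a11 (264 ± 229 to 6435 ± 1806 CPM). Of 14 pericentral markers 8 rose, or 13 when adjusted over the list alone (median 3.21, camera adjusted p 8.53e-07; adjusted p = 0.445 with an estimated correlation), among them glutamine synthetase, Glul (297 ± 175 to 1637 ± 45.8 CPM). Of 15 periportal markers 10 rose and 3 fell, or 11 and 3 when adjusted over the list alone (median 1.28, camera adjusted p 0.00254; adjusted p = 0.328 with an estimated correlation), among them Cps1, of the urea cycle (1030 ± 199 to 4476 ± 1706 CPM). Of 14 drug-metabolising cytochromes 8 rose, or 9 when adjusted over the list alone (median 3.23, camera adjusted p 2.24e-05; adjusted p = 0.235 with an estimated correlation). Cyp2c37 (5.33) and Cyp2c54 (6.80) rose on the log2 scale, though the Cyp2c family has close copies and its single values are uncertain. Of 15 bile acid genes 8 rose and 1 fell, or 9 and 1 when adjusted over the list alone (median 1.93, camera adjusted p 3.64e-05; adjusted p = 0.196 with an estimated correlation), and the 1 that fell was the exporter subunit Slc51b. Of 11 male-biased genes 7 rose, over all genes and when adjusted over the list alone (median 1.97, camera adjusted p 8.10e-05; adjusted p = 0.258 with an estimated correlation), such as Elovl3 (1.16 ± 0.885 to 50.2 ± 7.76 CPM).

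**Figure D3:**
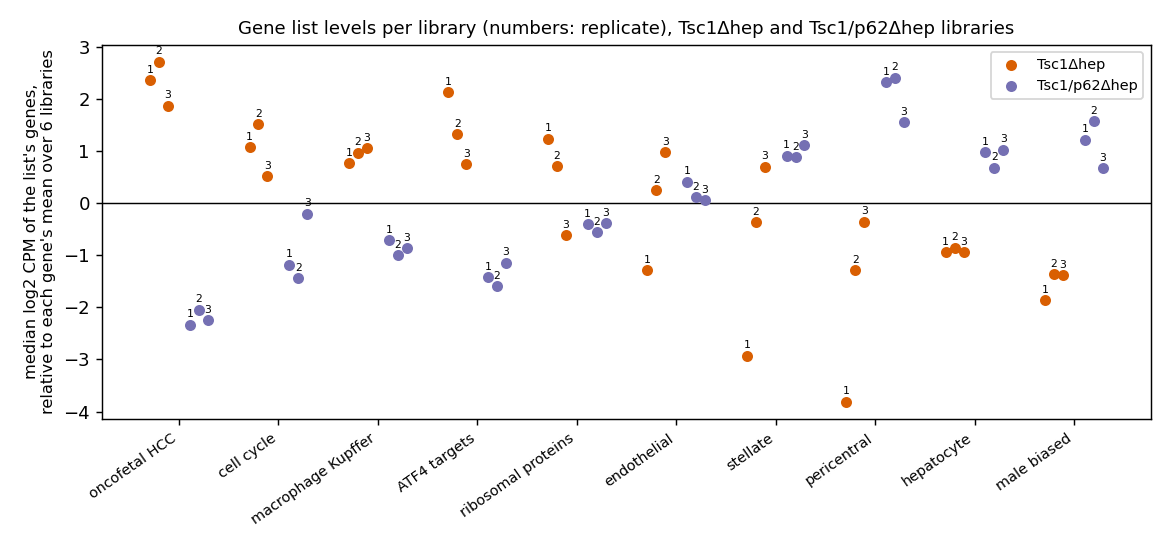
Median log2 CPM of the genes of selected lists, relative to each gene's mean over the 6 libraries, for each Tsc1Δhep and Tsc1/p62Δhep library, with a point per library. Oncofetal markers lay at 1.87 to 2.71 in Tsc1Δhep and at -2.33 to -2.05 in Tsc1/p62Δhep, and hepatocyte markers at -0.94 to -0.85 and at 0.68 to 1.03.

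Some metabolic lists were called higher in Tsc1/p62Δhep. Gluconeogenesis and glycogen genes had 6 of 12 that rose, over all genes and when adjusted over the list alone (median 0.93, camera adjusted p 0.00522; adjusted p = 0.313 with an estimated correlation), including G6pc, glucose-6-phosphatase (103 ± 18.9 to 482 ± 215 CPM). Lipogenesis had 2 of 14 that rose, by both counts (median 0.83, adjusted p 0.00224; adjusted p = 0.512 with an estimated correlation), and circadian genes 3 of 18, or 8 when adjusted over the list alone (median 0.88, adjusted p 0.00381; adjusted p = 0.372 with an estimated correlation). Cholesterol synthesis (3 of 23 rose by both counts, median 0.92, adjusted p 0.00961; adjusted p = 0.720 with an estimated correlation) lost its call without Tsc1/p62Δhep library 1 (0.0504) or 2 (0.0734). Its level was 0.75 and 0.91 in those libraries but -0.71 in Tsc1/p62Δhep library 3, below Tsc1Δhep libraries 2 and 3 (-0.13 and -0.26), and without library 3 the adjusted p was 4.48e-07. PPARα and fatty acid oxidation genes (4 of 24 rose and 1 fell by both counts, median 0.72, adjusted p 0.0437; adjusted p = 0.721 with an estimated correlation) lost theirs without Tsc1Δhep library 1 (0.107), Tsc1Δhep library 2 (0.0541) or Tsc1/p62Δhep library 3 (0.546), and their level in Tsc1Δhep library 3, at 0.26, lay above those of Tsc1/p62Δhep libraries 1 and 2, at -0.08 and 0.05. Ribosomal proteins (median -1.04, adjusted p 0.00198; adjusted p = 0.720 with an estimated correlation) had 1 of 32, Rpl37, that fell and 0 when adjusted over the list alone by edgeR. Their call was lost without Tsc1Δhep library 1 (0.0610), and their level in Tsc1Δhep library 3, at -0.61, lay below those of Tsc1/p62Δhep, at -0.55 to -0.39.

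In total 22 of 36 lists were called, 12 higher and 10 lower. With an estimated correlation 0 were called by camera (lowest adjusted p 0.196), and limma's fry called 18, of which 16 were also among the 22. For a change in either direction fry called 27. Fry tests a list's genes on their own and not against the other genes. As 3053 of 12620 genes were called here, its calls do not show a change particular to a list. The 14 lists not called were MYC targets (3 fell, or 1 when adjusted over the list alone), glycolysis (4 fell and 1 rose by both counts, Pfkp from 78.7 ± 17.1 to 1.47 ± 0.433 CPM), the unfolded protein response, p53 targets (4 fell and 2 rose by both counts), acute phase genes (5 fell and 2 rose, or 7 and 2), autophagy and lysosome (3 fell, or 0), the respiratory chain (2 rose, or 1), proteasome (1 rose and 1 fell, or 1 and 0), female-biased genes (2 rose and 2 fell by both counts), endothelial (1 fell, or 0), B and plasma cell (0 by both counts), neutrophil (2 fell, or 3), erythroid (1 rose by both counts) and immediate early genes (1 rose and 1 fell by both counts). The median and mean differed in sign for autophagy and lysosome (0.07 and -0.11), endothelial (0.14 and -0.08) and female-biased genes (-0.80 and 0.20), and camera's direction was up for erythroid markers (-0.86) and the respiratory chain (-0.15) against a negative median. Too few genes for a list test were left of T and NK cells (2, of which Ccl5 fell when adjusted over the list alone), adipocytes (1, Car3, which rose when adjusted over the list alone), pancreas (0) and muscle (0).

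**Figure D4:**
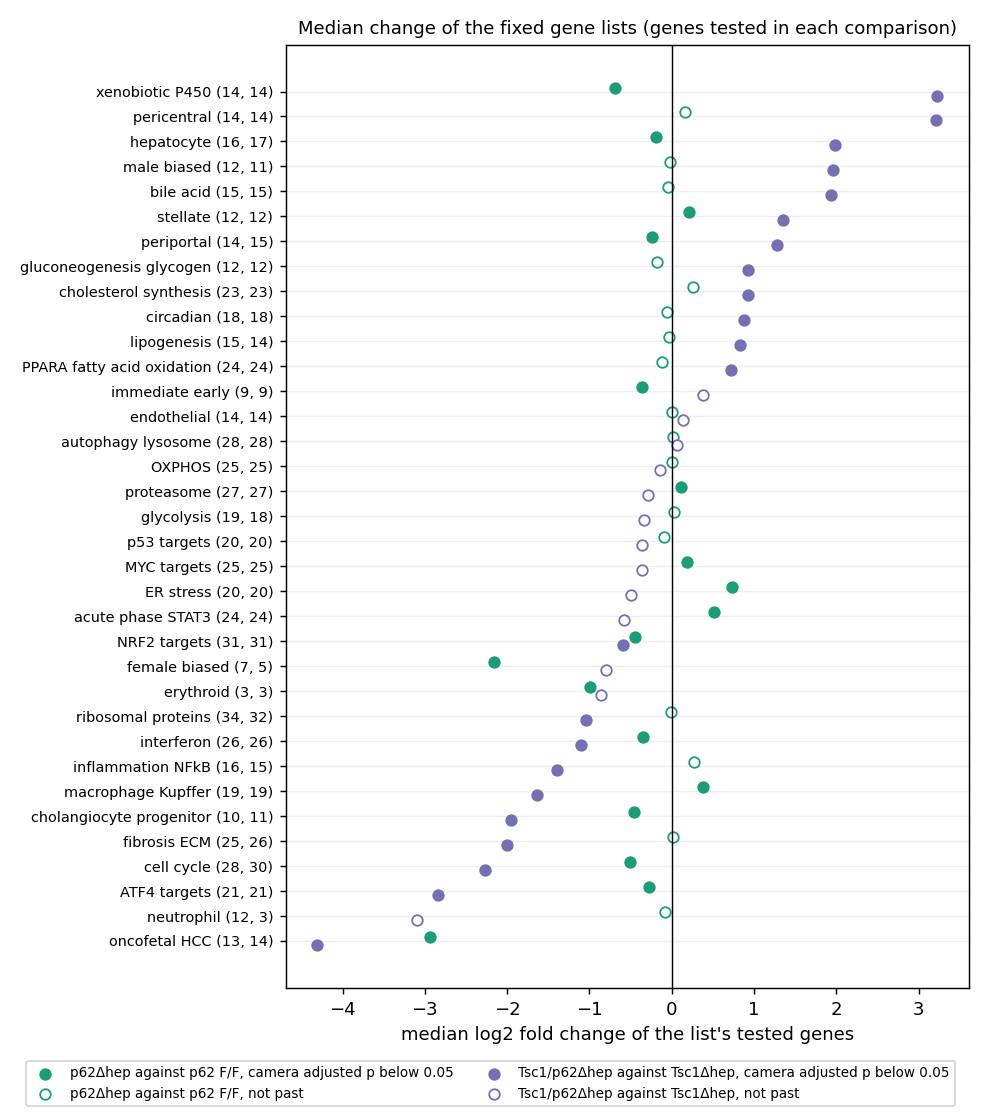
Median log2 fold change of each gene list tested in both comparisons, with p62 deletion in livers with Tsc1 intact and in livers lacking Tsc1, with filled points where camera's adjusted p was below 0.05. The oncofetal median was -2.94 and -4.31, and the unfolded protein response median 0.74 and -0.50.

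Whether the effect of losing p62 differed with Tsc1 was tested as the difference between both comparisons over all 12 libraries. Both groups lacking Tsc1 carried Cre and p62F/F did not, so an effect of Cre stays in this difference. Tsc1 genotype coincided with the table, so a diet, age, tissue or batch particular to either table that altered its contrast stays too. The 6 genes with the smallest p changed with p62 deletion in livers lacking Tsc1 and did not pass the test in livers with Tsc1 intact. Cd44 had a log2 difference of effects of -4.45, Ncoa7 of -4.40, Serpinb6a of -3.79 and Abr, a regulator of small GTPases, of -3.55. The cytochromes Cyp1a2 and Cyp2c67 had 5.55 and 4.39, and Cyp2c67 has close paralogs. Each had an adjusted p of 0.000132, and their log2 fold changes in livers with Tsc1 intact lay between -0.51 and 0.42 with adjusted p of 0.601 or more. The effect differed for 2127 of 13231 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, positively for 894 and negatively for 1233. Of the 2127, 1908 were also called in the comparison of Tsc1/p62Δhep with Tsc1Δhep. The count moved to 1408, 1241, 1274 and 1169 without p62F/F library 1, p62F/F library 2, p62Δhep library 2 and p62Δhep library 3, and to 4952, 1175 and 1217 without Tsc1Δhep library 3 and Tsc1/p62Δhep libraries 1 and 2. With Tsc1Δhep library 3 and Tsc1/p62Δhep library 1 both left out, chosen after seeing the data, it was 3904.

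The list test of this difference was added after seeing the data. By camera 20 of 37 lists were called, 10 shifted up and 10 down, and 0 with an estimated correlation (lowest adjusted p 0.0734). Those described here were chosen after their values were seen. Hepatocyte markers (9 of 17 with a positive difference, camera adjusted p 3.71e-08; adjusted p = 0.0734 with an estimated correlation) and pericentral markers (7 of 14, 2.12e-07; adjusted p = 0.361 with an estimated correlation) were shifted up where Tsc1 was lost. Macrophage markers (13 of 19 negative, 1.95e-05; adjusted p = 0.200 with an estimated correlation), ATF4 targets (11 of 21, 0.000108; adjusted p = 0.200 with an estimated correlation) and oncofetal markers (6 of 16, 0.000269; adjusted p = 0.282 with an estimated correlation) lay lower there. The unfolded protein response also differed, with 9 of 20 negative (0.00100; adjusted p = 0.544 with an estimated correlation). For NRF2 targets no difference was found by this test, with 7 of 31 negative and 1 positive (adjusted p 0.318), and for interferon-stimulated genes the adjusted p was 0.0696 with 6 of 26 negative.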

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

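The tests of other splits of the libraries in this part were planned, and the tests of hepatocyte share and of GC content and transcript length were chosen only after the result was seen.

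The change between libraries with and without p62 deletion differed between the Tsc1-deleted and Tsc1-intact groups for 2127 genes, by a test of the difference itself. Only p62F/F lacked Cre, so an effect of Cre stays in that difference and cannot be told apart. Tsc1 genotype coincided with the table. A diet, age, tissue or batch particular to either table that altered its contrast cannot be told apart either. Of the 6 genes with the smallest p, Cd44 (log2 difference of effects -4.45), Abr (-3.55), Ncoa7 (-4.40) and Serpinb6a (-3.79) had a lower, and Cyp1a2 (5.55) and Cyp2c67 (4.39) a higher, log2 fold change where Tsc1 was lost. When the libraries were regrouped 100 times, each time within a table, 6 regroupings, the real one included, gave as many genes, and the highest of the others gave 3029. Chance in the grouping is therefore not excluded at a share of 0.05. All 6 kept the real grouping of the Tsc1Δhep and Tsc1/p62Δhep libraries, and the regroupings that changed it called 0 genes by edgeR, against 2127 in the real grouping. Of the 100, 7 kept that grouping, the real one included. The others of these, with p62F/F and p62Δhep libraries regrouped, called 1949 to 3029 genes, and all but 1 of them called more than the real one. The count therefore follows the contrast between Tsc1Δhep and Tsc1/p62Δhep, and says less about how the p62F/F and p62Δhep libraries were grouped.

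The comparison of Tsc1/p62Δhep with Tsc1Δhep called 3053 genes and 22 lists. There are 10 splits of the 6 libraries, too few for a share below 0.05. The real split was the 1 with as many genes (highest other 0) and the 1 with as many lists (lowest other 10, highest other 18).

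In that comparison oncofetal, cell cycle and macrophage genes were lower and hepatocyte genes higher in Tsc1/p62Δhep. A lower share of hepatocytes in the Tsc1Δhep pieces would raise the markers of every other cell type alike. The median log2 fold change of macrophage minus endothelial markers was -1.77 (95% bootstrap interval -3.18 to -0.87). That interval resampled genes and not libraries, so it holds no spread between libraries and does not decide the question. A lower share of hepatocytes and a change in macrophages both stay open. A bias by GC content or transcript length is argued against as the whole cause, since 4 of the 4 lists kept their call and direction once each library's trend was removed. Their medians were -3.51, -1.29, -1.39 and 1.75 against -3.56, -1.48, -1.44 and 1.49 before, on the scale of log2(CPM + 1). Across genes the log2 difference had a Spearman rho of 0.21 with transcript length and 0.0069 with GC content. The ribosomal protein median, outside these lists, shrank from -0.88 to -0.58 with the removal, so part of that fall went with the trend. Whether the Tsc1Δhep pieces held tumour, and whether diet, age, strain background, sequencer or library batch differed between the groups, was not tested and stays open. The word NORMAL in the name of the deposited counts may bear on the tumour question, but what it refers to is not explained.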

How the results depend on the processing

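The settings named as added were chosen after seeing the data. The cause of each change was not tested, except that leaving out a library leaves fewer samples.

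For p62Δhep against p62F/F, the 0 genes higher and 2 lower became 32 and 150 with DESeq2. The count lower was 4 with robust dispersion, 4 with limma on log2(CPM + 1), 1 with all 12 libraries in 1 fit and, added, 5 with 1 surrogate variable. Limma with the GC and length trend removed, also added, called 4 lower, as limma without that removal did. Leaving out each library gave 0 to 1 higher and 1 to 48 lower.

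For Tsc1/p62Δhep against Tsc1Δhep, the 1167 genes higher became 1768 with DESeq2 and, added, 2150 with 1 surrogate variable. Limma on log2(CPM + 1) called 1357 higher, and 2262 with the GC and length trend removed, added. With all 12 libraries in 1 fit 2249 were higher and 2952 lower, against 1886 lower. Leaving out each library gave 351 to 2686 higher and 760 to 3139 lower. The interaction's 2127 genes became 1169 to 4952 when leaving out each library and 3904 without Tsc1Δhep library 3 and Tsc1/p62Δhep library 1, added.

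The lists called went from 18 and 22 to 0 and 0 with an estimated correlation, and with fry to 0 for p62Δhep. They were 15 to 16 and 20 to 24 when leaving out each library, newly called lists included. Of the 18 and 22, 11 to 15 and 19 to 22 were called again in the same direction.

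Same-numbered libraries did not deviate together (correlations -0.47 to 0.04 and -0.11 to -0.07), and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate block, 0 and 1 genes were called for p62Δhep, 649 and 1198 for Tsc1/p62Δhep and 1580 for the interaction, and 19 and 22 lists.

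Of the named genes, Tsc1 in p62Δhep changed sign, with values from -0.10 to 0.20 when leaving out each library. Nfe2l2 ranged from -0.21 to 0.0719 there and from -0.0386 to 0.114 in Tsc1/p62Δhep, where it was -0.00376 with a mean of at least 50 counts. None of these had passed the test. Over the alternatives fixed in advance, the 13 genes named in p62Δhep kept direction and side of the threshold in 152 of 180 fits (7 weaker, 16 stronger, 5 reversed), the 96 in Tsc1/p62Δhep in 1245 of 1342 (88, 6, 3) and the 6 of the interaction in 114 of 114. In p62Δhep and in Tsc1/p62Δhep, 2 combinations each of gene and setting gave no value. DESeq2's size factors and no low-count filter moved none of the 3 counts of genes called by over 1.5 times, and neither did leaving out Rn45s in the 2 comparisons within a table, the only ones where it was run. The files held counts, so the alternatives for normalized values were not run. With these depths and this spread between libraries, 2-fold changes were mostly missed in simulation, where 64 to 67 genes were changed at each fold. The real comparison of Tsc1/p62Δhep with Tsc1Δhep called 3053 genes, some by 2-fold or less. The simulated shares therefore do not give its recovery.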

Other observations

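The counts of splits for the genes and lists called in p62Δhep against p62F/F were planned, and the other tests, the splits for genes lower in both comparisons included, were chosen only after the results were seen, as were the genes singled out.

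Set side by side as plain CPM, without a test across tables, several genes stood far higher in Tsc1Δhep than in the other 3 groups. Cbr3 was at 7.43 ± 1.15 CPM in p62F/F, 0.802 ± 0.201 in p62Δhep, 154 ± 120 in Tsc1Δhep and 1.00 ± 0.538 in Tsc1/p62Δhep. Nqo1 was at 12.0, 4.13, 78.7 and 9.21 CPM in the same order, and Sqstm1 at 342, 16.6, 1126 and 15.2 CPM. Apobec3, a cytidine deaminase gene with the smallest p of the comparison of Tsc1/p62Δhep with Tsc1Δhep, was at 3.46, 2.77, 87.9 and 1.28 CPM. Whether its high level in Tsc1Δhep came with a different strain background was not tested. Glutamine synthetase, Glul, was lowest in Tsc1Δhep, at 1578, 1774, 345 and 1451 CPM. Malat1, a nuclear RNA, was at 1097, 1059, 94.9 and 172 CPM, so it differed by table, which coincides with the Tsc1 genotype. The Y-linked gene Uty was counted in each of the 12 libraries, at 16.1 to 27.2 CPM. Another Y-linked gene, Kdm5d, was at 1.66 CPM in Tsc1Δhep library 3 and at 8.20 to 24.4 CPM in the other libraries.

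Among 12100 genes tested in both comparisons, 586 were lower at an unadjusted p below 0.05 in p62Δhep and 1569 were called lower in Tsc1/p62Δhep. Lower in both were 240, against 76.0 if the lists were independent, and higher in both were 39, against 36.2. A further 52 went in opposite directions. With the 6 libraries of the p62F/F and p62Δhep table split in 10 ways, too few for a share below 0.05, the real split was the 1 with as many genes lower in both, and the 2 highest of the others gave 166 and 153. These were against 43.2 and 42.8 if independent, so an excess over independence is not specific to the real split. Of the 11 NRF2 targets that fell over the list alone in p62Δhep, 8 were called lower in Tsc1/p62Δhep, as were 4 of 5 interferon-stimulated genes. Over the whole lists, 12 of 31 NRF2 targets and 13 of 26 interferon-stimulated genes were called lower there. Of oncofetal markers tested in both, 8 fell over the list alone in p62Δhep and 1, Peg3, rose. All of these were called lower in Tsc1/p62Δhep, as were all 14 markers of that list tested in it. Of the 10 unfolded protein response genes that rose in p62Δhep over the list alone, 0 were called lower there by edgeR, and 9 of the list's 20 had a negative interaction.

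The comparison of p62Δhep with p62F/F called 2 genes and 18 lists. Of the 10 splits of its 6 libraries, too few for a share below 0.05, the real split was the 1 with as many genes (highest other 0). As many lists were given by 3, the real one included (lowest other 10, highest other 18). For the NRF2 targets the camera adjusted p was 3.72e-09 in the real split and at the lowest 0.00104 in the others. For the same list in Tsc1/p62Δhep against Tsc1Δhep it was 0.00434 in the real split, and another split gave a smaller one, 0.00103.

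NRF2 targets were lower in p62Δhep as a list. That the camera call at a preset correlation rested on 1 library is argued against, since the highest camera adjusted p over the fits that left out each library was 2.98e-07. Other splits of these libraries also put the list below 0.05, at the lowest 0.00104, so staying below 0.05 would not by itself decide this. A lower share of hepatocytes in p62Δhep stays open. NRF2 targets minus hepatocyte markers gave a median log2 difference of -0.26 with a 95% bootstrap interval of -0.80 to 0.01, resampling genes and not libraries. The list's call was lost with an estimated correlation (adjusted p 0.586).

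Ifi202b had 43, 66 and 66 counts in p62F/F libraries 1 to 3 and 0 in each library of the other 3 groups. Low depth is argued against, since the p62F/F share would give 182 counts over the p62Δhep libraries. A strain variant carried with a chromosome segment may account for it and stays open: of the 40 nearest tested genes 6 were at an unadjusted p below 0.05, against 8.10% of the others (Fisher's exact test, one-sided p 0.102). A segment need not change its other genes, so this test excludes nothing.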
